A study of Homo sapiens with 12 samples.

How the data were processed

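Gene expression was measured by RNA sequencing in 12 samples of the hepatoma lines Huh-7 and MHCC-97H, 3 with the control small interfering RNA si-NC and 3 with si-CENPU in each line. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, RNA was taken up with a PureLink kit and libraries were made with an Illumina TruSeq RNA kit. The values are TPM as deposited by the authors, 1 column per sample over 60664 Ensembl gene identifiers. Per the submitters' processing notes the tools were HISAT2 and StringTie on GRCh38.p13, with no versions. The annotation release, the strand setting and any filter are not given in the sources used here, so overlapping and antisense genes cannot be told apart from these values. The TPM columns summed to between 998416 and 999065. No column was identical to another. TPM keeps no sequencing depth, so the depth of each library is unknown, and no counting interval or detection limit is given. An exact 0 in such a table can be a failed estimate, and genes that all dividing cells use were among the zeros of Huh-7. For genes at or near 0 the value of each library is given instead, and a gene is said to be listed at 0.

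Groups and replicate numbers were taken from the sample titles. Gene symbols were matched by Ensembl identifier, for 60447 of the 60664 identifiers. Coordinates, gene types and transcript GC content came from GENCODE release 29 on GRCh38, which gave a GC value for 10970 (98.9%) of the tested genes.

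TPM was put on the scale log2(TPM + 1), and fold changes are on this scale, which understates the change of low genes. Genes with a mean TPM of at least 1 over the 12 samples were tested, 11088 in all. A linear model with 1 mean per group was fitted to all 12 samples with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation with a mean-variance trend. The 12 samples shared 1 estimate of the spread per gene. The contrasts were si-CENPU minus si-NC in each line, and MHCC-97H minus Huh-7 for the difference of responses. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p below 0.05 were called. The model, the filter, the contrasts, the gene lists and the rule for named genes were fixed before the data were examined.

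CENPU and E2F1 averaged under 1 TPM, so the planned limma test did not reach them. For these and E2F6, differences of group means on the log2 scale are given with exact two-sided permutation tests of the 3 against 3 values, whose smallest p is 0.1. An exact test within both lines together, with a smallest p of 0.005, was added after the values were seen.

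The rule for named genes took CENPU, E2F1 and E2F6, then per line up to 8 called genes in each direction with the largest change whose groups did not overlap. It also took genes called in both lines, the 6 genes with the smallest adjusted p of the difference between lines, and up to 4 members per list and line with the smallest adjusted p. Since few genes were called, some genes outside the rule are named and said to be chosen after their values were seen. Of 28 fixed gene lists, 23 had at least 5 tested members. Each was tested in each line with camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and the 46 tests were adjusted together. Camera compares a list with all other tested genes, so its direction can differ from the sign of a list's own median. The 5 lists of other cell types had too few tested members and are given as levels.

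The scripts were tested on simulated data, in which 200 genes per line were changed by known amounts at the spread of these samples. Of the genes called there, 7.38% in Huh-7, 4.62% in MHCC-97H and 3.66% for the difference between lines had not been changed. The simulated noise was independent between genes, whereas genes of a real library can deviate together, and changes were not stopped at 0 TPM. Shares from this simulation hold for its setting and can be too favourable for these data. The alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a mean TPM of at least 5, trimmed-mean and quantile scaling, and rescaling without mitochondrial genes and the 100 most abundant genes. Further ones were a fit of each line alone, the replicate number as a block, moderation without a trend or with robust settings, an added limit of 2-fold, and leaving out each library in turn. A correction for transcript GC content by a smoothed trend per library, a filter within each line, a test of protein-coding genes only, the average of both lines, and list tests with an estimated correlation under each alternative that gave a list call were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.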

Results

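RNA was sequenced from 12 samples of cultured human hepatoma cells, 3 in each of 4 groups. Huh-7 is a hepatoma line that makes many plasma proteins of the liver, and MHCC-97H is a hepatocellular carcinoma line. Each line was transfected either with a small interfering RNA against CENPU (si-CENPU) or with the control small interfering RNA named si-NC. CENPU encodes a subunit of the constitutive centromere-associated network, the inner kinetochore complex that stays on centromeric chromatin. The comparisons were si-CENPU against si-NC within each line, and the difference of that response between the lines. Nothing in the sample descriptions said whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Expression was given as TPM, the transcript abundance scaled to a fixed total per library, for 60664 gene identifiers, a unit that keeps no sequencing depth, and between 18639 and 20900 genes per library lay above 0. Huh-7 si-NC replicate 1 stood apart from the other libraries of its line, with a mean correlation to them of 0.965, against 0.975 to 0.978 for the others, and 1.43% of its TPM in mitochondrially encoded genes. Libraries also deviated from their line mean with transcript GC content. The Spearman rho ran from -0.516 in MHCC-97H si-NC replicate 1 to 0.456 in MHCC-97H si-NC replicate 3.

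The targeted gene was listed lower after si-CENPU in both lines, at 0.11 to 1.17 TPM. Values this near 0 can be poor estimates, so the percentages below may not measure the size of the loss. In Huh-7, CENPU (ENSG00000151725; GRCh38 chromosome 4, 184694618 to 184734133, minus strand) stood at 0.643 ± 0.171 TPM in si-NC and 0.243 ± 0.181 TPM in si-CENPU (SD, n = 3), which was 62.2% lower. Its libraries read 0.56, 0.84 and 0.53 TPM with si-NC and 0.17, 0.11 and 0.45 TPM with si-CENPU. In MHCC-97H it stood at 0.963 ± 0.181 and 0.303 ± 0.127 TPM (SD, n = 3), or 68.5% lower, with libraries at 1.17, 0.83 and 0.89 TPM against 0.22, 0.45 and 0.24 TPM. All 6 si-CENPU libraries lay below the si-NC libraries of their own line. On the log2(TPM + 1) scale, which understates the change of genes this low, the differences were -0.41 in Huh-7 and -0.59 in MHCC-97H. Within a line the two-sided exact permutation p was 0.1, the smallest that 3 against 3 samples allow. An exact test that permuted labels within both lines together, chosen after the values were seen, gave a p of 0.005, the smallest possible, and 0.0075 after adjustment over the 3 genes tested this way. CENPU averaged 0.538 TPM over the 12 samples and was below the expression limit of the gene-wide fit. With that limit lifted, its limma adjusted p was 0.955 in Huh-7 and 0.537 in MHCC-97H.

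E2F1, a transcription factor that drives entry into S phase, was also listed lower in both lines, at levels near 0. Its libraries (ENSG00000101412; chromosome 20, 33675683 to 33686404, minus strand) read 0.23, 0.18 and 0.32 TPM in Huh-7 si-NC and 0.13, 0.06 and 0.04 TPM in Huh-7 si-CENPU. In MHCC-97H they read 0.3, 0.1 and 0.2 TPM with si-NC, and 0.09, 0 and 0 TPM with si-CENPU. The differences on the log2(TPM + 1) scale were -0.21 and -0.22. The exact permutation p was 0.1 in each line, and 0.005 over both lines together, with an adjusted p of 0.0075. In MHCC-97H the order of the groups rests on exact zeros, which can be failed estimates, and on 0.09 against 0.1 TPM. These permutation p-values therefore depend in part on values that may not be measured levels. With the expression limit of the gene-wide fit lifted, the limma adjusted p of E2F1 was 0.946 in Huh-7 and 0.928 in MHCC-97H. E2F6, a repressor of the same family, did not differ by more than the replicate spread (ENSG00000169016; chromosome 2, 11444375 to 11466177, minus strand). It stood at 0.843 ± 0.146 and 1.02 ± 0.376 TPM in Huh-7 (SD, n = 3; exact permutation p = 0.6), and at 2.03 ± 0.935 and 1.69 ± 0.356 TPM in MHCC-97H (SD, n = 3; exact permutation p = 0.7). Over both lines its exact permutation p was 0.965.

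**Figure D1:**
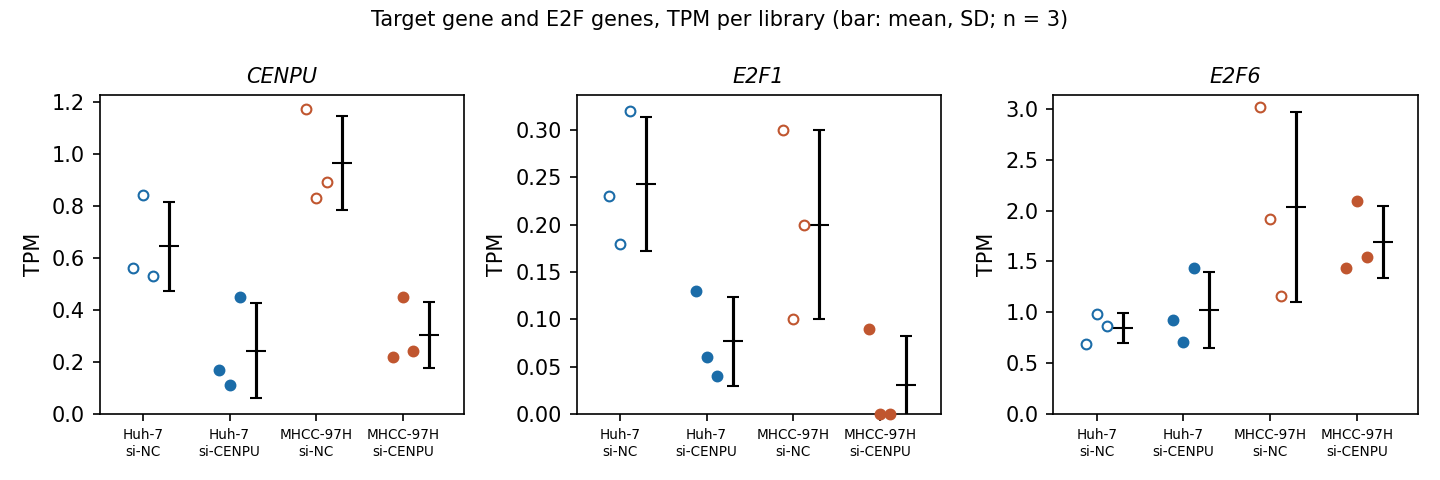
TPM of CENPU, E2F1 and E2F6 in each of the 12 libraries (open dots si-NC, filled dots si-CENPU), with mean and SD beside each group of 3; the y axis is TPM and starts at 0, where the E2F1 bar of MHCC-97H si-CENPU is clipped. In both lines the si-CENPU libraries of CENPU (0.11 to 0.45 TPM) and of E2F1 (0 to 0.13 TPM) lie below their si-NC libraries, while those of E2F6 overlap them.

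In Huh-7, 1 gene passed the threshold after si-CENPU. MAP2K4, the kinase MKK4 that activates JNK and p38, rose from 0.690 ± 0.346 to 4.77 ± 0.403 TPM (SD, n = 3), a 6.91-fold difference of means. Its 3 si-CENPU libraries, at 4.33, 5.12 and 4.86 TPM, all lay above the si-NC libraries at 0.42, 1.08 and 0.57 TPM. The gene (ENSG00000065559) lies on chromosome 17 from 12020824 to 12143830, on the plus strand. Its log2 change was 1.79 (SE 0.168; limma adjusted p = 0.00446 over 11088 genes). The call was lost when Huh-7 si-CENPU replicate 2 was left out (adjusted p = 0.0531) and when the line was fitted alone (adjusted p = 0.455, or 0.298 with the filter within that line). It held in 21 of the 25 alternative fits that tested the gene, over which the adjusted p ran from 4.011e-04 to 0.455, and a limit of a mean of 5 TPM left the gene untested.

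Other genes with small p-values in Huh-7 did not pass, and were chosen after their values were seen except for NR1H3, which the rule on the difference between lines named. NR1H3, the oxysterol receptor LXR-alpha, stood at 6.02 ± 2.32 TPM in si-NC and 1.38 ± 0.132 TPM in si-CENPU (log2 change -1.50, SE 0.226, limma adjusted p = 0.211). It lies on chromosome 11 from 47248300 to 47269032. EMC6, a subunit of the endoplasmic reticulum membrane protein insertion complex, stood at 785 ± 36.4 and 1139 ± 57.5 TPM (log2 0.54, adjusted p = 0.287). OGFR, the opioid growth factor receptor, stood at 17.4 ± 1.86 and 28.0 ± 2.19 TPM (log2 0.66, adjusted p = 0.287), and the adrenergic receptor gene ADRA2A at 1.20 ± 0.421 and 3.37 ± 0.875 TPM. In all, limma called 1 gene higher and 0 lower in Huh-7. Without si-NC replicate 1, the library that stood apart, it called 3 genes, MAP2K4, NR1H3 and GEM. At an unadjusted p below 0.05 there were 507 genes, 283 higher and 224 lower, where chance alone gives 554.4. That count lay above 554.4 under some settings, with 804 without Huh-7 si-CENPU replicate 1, 807 after the GC correction, 753 with quantile normalization and 660 with trimmed-mean scaling. The spread of this count under chance was not computed. The groups did not overlap for 848 genes, or 7.65%. Chance gives 10% for values without ties and less where values such as zeros tie, so the shares cannot be compared directly. Scaling with a trimmed mean gave 1 higher and 1 lower, and quantile normalization gave 2 higher and 1 lower, NR1H3 being the lower gene in both. After the GC correction, which was added after seeing the data, NR1H3 and OGFR passed (limma adjusted p = 0.0232 each), while EMC6 and ADRA2A did not. Simulated changes of 0.5 log2 units were recovered for 13.6% of genes in this line, those of 1 unit for 58.2% and those of 2 units for 97.0%, over the same 11088 genes. The simulated noise was independent between genes and 200 genes were changed per line, so recovery in these data can be lower.

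The gene groups fixed before the data were examined gave no call as groups in Huh-7. No list member passed the threshold over all genes, and 4 passed when adjusted over the list alone. None of the 46 camera tests, over 23 lists with enough tested members and both lines, passed after adjustment, and none did with an estimated correlation (smallest adjusted p = 0.988). The subunits of the inner kinetochore, to which CENPU belongs, had 3 members past the threshold adjusted over the list alone and 0 over all genes, among 14 tested, of which 7 averaged under 0.5 TPM in this line. These were CENPH at 0.440 ± 0.0400 and 1.10 ± 0.191 TPM, the CENP-A deposition factor OIP5 at 2.37 ± 0.605 and 6.07 ± 2.67 TPM, and CENPM at 0.07, 0.32 and 0.38 TPM against 0.6, 0.67 and 0.61 TPM, each with a list-adjusted p of 0.0276. CENPT went the other way, with 0.483 ± 0.0379 and 0.180 ± 0.0608 TPM. CENPW was listed at 0, 774.17 and 146.03 TPM in the si-NC libraries and at 767.94, 778.95 and 1067.93 TPM in the si-CENPU libraries (log2 change 4.15, unadjusted p = 0.0377, list-adjusted p = 0.106), so its si-NC level depended on single libraries. The list test had an adjusted p of 0.279 (unadjusted p = 0.0182, and 0.273 with an estimated correlation). The outer kinetochore and spindle checkpoint list, with 3 tested members averaging under 0.5 TPM in this line, had 1 of 19 at an unadjusted p below 0.05. This was KNTC1, listed at 0, 0.03 and 0.02 TPM against 0.56, 1.29 and 0.2 TPM (camera adjusted p = 0.628).

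Cell cycle genes of Huh-7 gave no call, but some tested members were listed near 0 in this line. Those averaging under 0.5 TPM numbered 3 for G2/M and mitosis, 7 for the E2F and RB family and 3 for p53 targets. They numbered 3 for apoptosis and 1 for homologous recombination. Such values say little about a response. Of 35 tested G2/M and mitosis genes, limma called 0, and 0 reached an unadjusted p below 0.05 (camera adjusted p = 0.843). The securin PTTG1 stood at 95.03 ± 28.9 and 122 ± 13.3 TPM, and the spindle midzone gene PRC1 at 8.27 ± 0.372 and 6.74 ± 1.75 TPM. Of 40 tested G1/S and replication genes, 10 of which averaged under 0.5 TPM in Huh-7, 0 were called and 0 reached an unadjusted p below 0.05 (camera adjusted p = 0.628), with RFC4 at 5.42 ± 1.19 and 3.89 ± 0.941 TPM. Of 18 E2F and RB family genes 1 was at an unadjusted p below 0.05, CDKN2A, listed at 0, 0.06 and 0 TPM against 0.14, 0.27 and 0.14 TPM (camera adjusted p = 0.970). Of 18 p53 targets 1 did so, PLK3, at 6.35 ± 1.08 and 8.03 ± 0.620 TPM (camera adjusted p = 0.939). Homologous recombination genes had 1 of 17, the nuclease gene MUS81 at 11.8 ± 0.582 and 14.2 ± 1.15 TPM (camera adjusted p = 0.970). Apoptosis genes had 3 of 25, with the BH3-only gene BIK at 15.2 ± 1.25 and 18.3 ± 0.682 TPM and BOK at 16.1 ± 2.64 and 12.7 ± 1.94 TPM (camera adjusted p = 0.970).

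Among signalling and stress lists of Huh-7, 1 of 7 Notch and Hedgehog genes passed the threshold adjusted over the list alone and 0 did over all genes. The receptor gene NOTCH1 stood at 2.22 ± 0.836 and 0.713 ± 0.3 TPM (log2 -0.89; list-adjusted p = 0.00773; limma adjusted p over all genes = 0.615), and the list test had an adjusted p of 0.970. The unfolded protein and integrated stress list had 2 of 23 members at an unadjusted p below 0.05, CRELD2 at 11.6 ± 0.892 and 16.7 ± 1.92 TPM and TRIB3 at 58.5 ± 4.03 and 70.1 ± 3.62 TPM (camera adjusted p = 0.628). The interferon list had 1 of 14, the RNA sensor gene OAS3 at 5.19 ± 0.388 and 3.89 ± 0.407 TPM (camera adjusted p = 0.829). Of 15 NF-kB and inflammatory genes 12 had positive log2 changes and 0 reached an unadjusted p below 0.05, with the chemokine gene CXCL1 at 17.1 ± 3.98 and 20.7 ± 1.70 TPM (camera adjusted p = 0.460). Wnt targets had 1 of 8, MYC at 3.87 ± 1.78 and 1.70 ± 1.36 TPM (camera adjusted p = 0.628).

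Liver and metabolic lists of Huh-7 likewise held 0 calls by limma. Hepatocyte functions had 1 of 25 at an unadjusted p below 0.05, haptoglobin (HP) at 2.50 ± 0.317 and 1.85 ± 0.0351 TPM, beside APOA1 at 4619 ± 283 and 4088 ± 154 TPM (camera adjusted p = 0.970). Fetal liver genes had 1 of 11, the keratin gene KRT7, with all values at or under 0.44 TPM (camera adjusted p = 0.970). Epithelial junction genes had 2 of 14, among them CLDN3 at 6.99 ± 0.895 and 5.59 ± 0.266 TPM, and mesenchymal and matrix genes had 0 of 21, with the integrin ITGA5 at 9.57 ± 1.43 and 7.22 ± 2.21 TPM (camera adjusted p = 0.970 for both lists). Cholesterol genes had 0 of 24, with mevalonate kinase (MVK) at 33.1 ± 1.82 and 29.2 ± 1.55 TPM (camera adjusted p = 0.818), and fatty acid genes had 0 of 15, with SREBF1 at 30.1 ± 3.37 and 31.4 ± 2.36 TPM (camera adjusted p = 0.970). Glycolysis and hypoxia genes had 0 of 26, with NDRG1 at 37.4 ± 16.9 and 22.4 ± 2.98 TPM (camera adjusted p = 0.970). Ribosomal protein genes had positive log2 changes for 36 of 51 members (camera adjusted p = 0.279; unadjusted p = 0.0170, and 0.228 with an estimated correlation). The lone member at an unadjusted p below 0.05 was RPS7, which went the other way, at 1588 ± 546 and 557 ± 396 TPM. Nuclear respiratory chain genes had 2 of 35, NDUFS7 at 1166 ± 63.1 and 1004 ± 86.0 TPM and NDUFA8 at 25.9 ± 2.61 and 34.5 ± 5.00 TPM (camera adjusted p = 0.829). Mitochondrially encoded genes had 0 of 13, with MT-ND1 at 1904 ± 592 and 2031 ± 70.1 TPM (camera adjusted p = 0.970). The median, the mean and the test direction differed in sign for 8 lists in Huh-7: interferon, fatty acid, fetal liver, mesenchymal, epithelial junction, Notch and Hedgehog, apoptosis and mitochondrially encoded genes.

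In MHCC-97H, 1 gene passed the threshold after si-CENPU, a different one. ADAM15, a membrane-anchored metalloproteinase and disintegrin, rose from 59.7 ± 3.41 to 102 ± 1.76 TPM (SD, n = 3), a 1.71-fold difference of means. The 3 si-CENPU libraries lay between 100.52 and 104.03 TPM and the si-NC libraries between 57.7 and 63.63 TPM. The gene (ENSG00000143537) lies on chromosome 1 from 155050566 to 155062775, on the plus strand. Its log2 change was 0.77 (SE 0.0900; limma adjusted p = 0.0399). With 1 library left out, the call held in 2 of 12 fits, those without Huh-7 si-NC replicate 1 and without MHCC-97H si-NC replicate 2, and the adjusted p ranged from 0.0349 to 0.323. It was also lost when the line was fitted alone (adjusted p = 0.193), without the variance trend (0.147), with a pseudocount of 0.1 (0.0572) and under an added limit of 2-fold, which the change did not reach. It held in 11 of the 26 alternative fits, over which its adjusted p ran from 0.00653 to 0.467.

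Further genes of MHCC-97H with small p-values, chosen after their values were seen, did not pass. MKNK2, a kinase of the translation factor eIF4E, stood at 19.98 ± 0.428 and 32.6 ± 2.90 TPM (log2 0.68, limma adjusted p = 0.161). PCNX3 stood at 18.3 ± 0.637 and 30.4 ± 2.51 TPM (log2 0.70, adjusted p = 0.161), and EMC6 at 222 ± 23.8 and 327 ± 22.2 TPM (log2 0.56, adjusted p = 0.161). GANAB, the catalytic subunit of glucosidase II, stood at 21.4 ± 4.51 and 44.6 ± 7.36 TPM (log2 1.03, adjusted p = 0.420), and TMEM9B at 5.42 ± 1.24 and 2.40 ± 0.464 TPM (log2 -0.91, adjusted p = 0.420). In all, limma called 1 gene higher and 0 lower in MHCC-97H. At an unadjusted p below 0.05 there were 379 genes, 184 higher and 195 lower, where chance alone gives 554.4. Without MHCC-97H si-NC replicate 3 the count was 791, above 554.4, and its spread under chance was not computed. The groups did not overlap for 771 genes, or 6.95%, where chance gives 10% for values without ties and less with ties. Trimmed-mean scaling and quantile normalization each gave 6 higher and 1 lower, ADAM15, MKNK2, PCNX3 and GANAB being among the higher and TMEM9B the lower gene in both. After the GC correction, added after seeing the data, MKNK2, PCNX3, GANAB and TMEM9B passed (limma adjusted p from 0.00975 to 0.0106), while EMC6 did not. Simulated changes of 0.5 log2 units were recovered for 18.2% of genes, those of 1 unit for 71.6% and those of 2 units for 95.5%, over the same 11088 genes. With the same simulated noise as for Huh-7, recovery in these data can be lower here too.

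**Figure D2:**
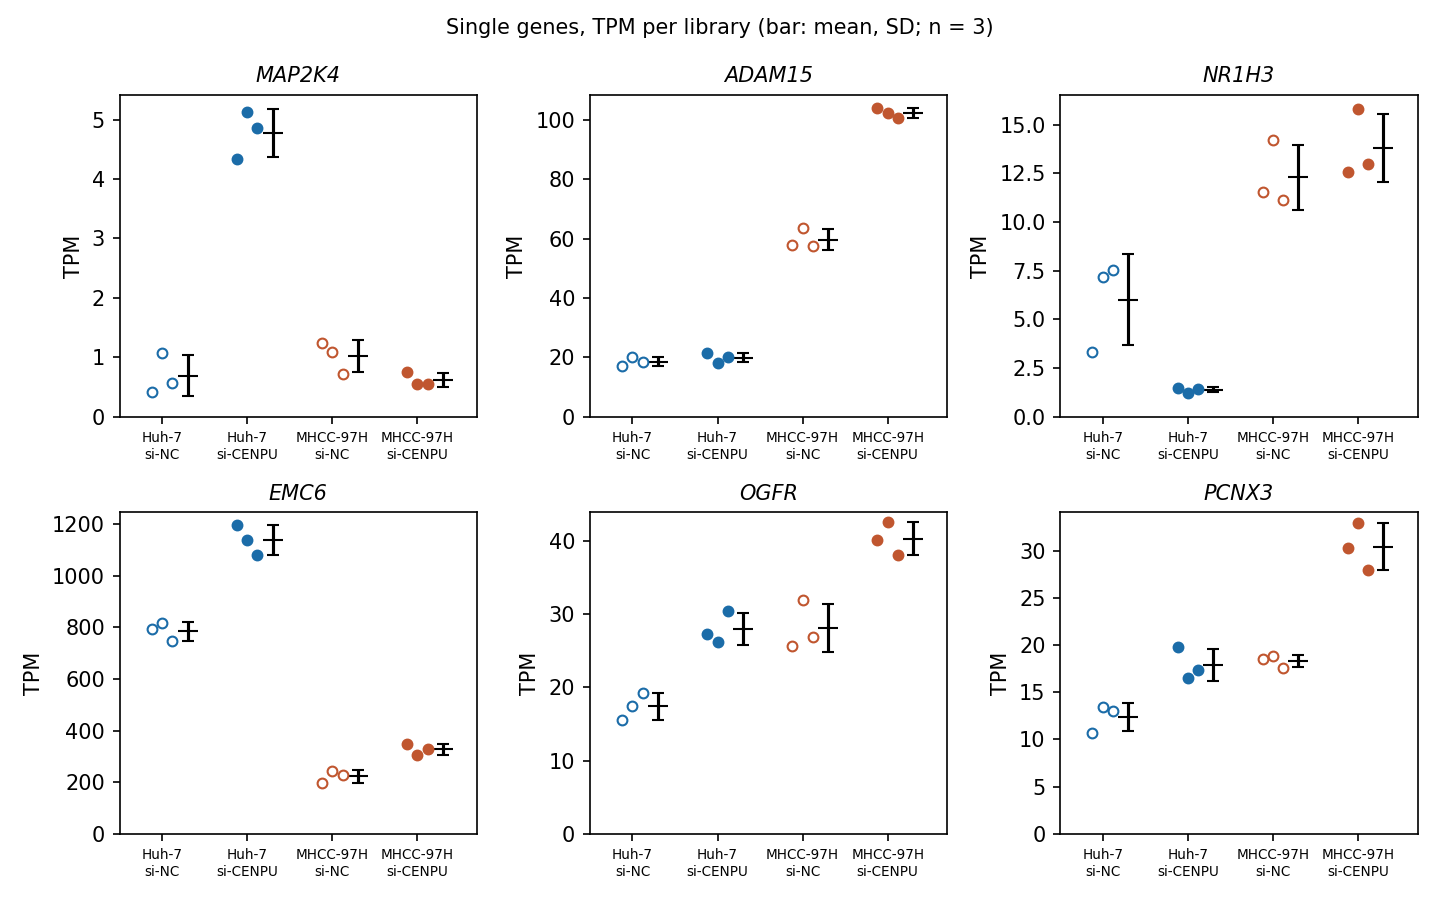
TPM of MAP2K4, ADAM15, NR1H3, EMC6, OGFR and PCNX3 in each of the 12 libraries (open dots si-NC, filled dots si-CENPU), with mean and SD beside each group of 3; each y axis is TPM and starts at 0. MAP2K4 is higher with si-CENPU in Huh-7 (0.690 against 4.77 TPM) and ADAM15 in MHCC-97H (59.7 against 102 TPM), and EMC6, OGFR and PCNX3 are higher in the si-CENPU libraries of both lines.

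The gene groups gave no call as groups in MHCC-97H either. No list member passed the threshold over all genes with limma, and 1 passed when adjusted over the list alone. This was TRIB3, a pseudokinase of the integrated stress response, at 43.6 ± 3.10 and 56.2 ± 3.91 TPM (log2 0.36; list-adjusted p = 0.0469; adjusted p over all genes = 0.740). TRIB3 was the lone member of its 23-gene list at an unadjusted p below 0.05 in this line (camera adjusted p = 0.970). The smallest list p was that of hepatocyte functions, at an adjusted p of 0.0949 (unadjusted p = 0.00206, and 0.275 with an estimated correlation). Of its 25 tested members 20 averaged under 0.5 TPM in MHCC-97H, and the member with the smallest p, APOA1, read 0.25, 0.15 and 0.29 TPM against 0.64, 0.42 and 0.58 TPM. Under the settings where that list test passed, its adjusted p ran from 4.315e-05 at a pseudocount of 0.1 to 0.0437 without Huh-7 si-NC replicate 1. With an estimated correlation under the same settings it passed in none (adjusted p from 0.295 to 0.999). Fetal liver genes had 0 of 11 members at an unadjusted p below 0.05, with KRT7 at 580 ± 20.3 and 551 ± 37.0 TPM (camera adjusted p = 0.970).

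Cell division genes of MHCC-97H gave no call. Of 14 inner kinetochore genes 0 reached an unadjusted p below 0.05, with OIP5 at 12.2 ± 1.70 and 9.70 ± 2.29 TPM and CENPT at 20.4 ± 0.231 and 18.4 ± 2.75 TPM (camera adjusted p = 0.829). Of 19 outer kinetochore and checkpoint genes 0 did so, with SKA1 at 2.80 ± 0.661 and 1.93 ± 0.392 TPM (camera adjusted p = 0.970). Of 35 G2/M and mitosis genes 27 had negative log2 changes and 0 reached an unadjusted p below 0.05, with the cytokinesis gene ANLN at 9.49 ± 2.61 and 7.74 ± 0.630 TPM (camera adjusted p = 0.829). The median change of this list was -0.09 on the log2 scale, where that of all tested genes was -0.05. G1/S and replication genes had 1 of 40, thymidine kinase (TK1) at 130 ± 12.7 and 155 ± 8.86 TPM (camera adjusted p = 0.818). E2F and RB family genes had 1 of 18, E2F5 at 2.31 ± 0.751 and 1.30 ± 0.130 TPM, beside the CDK inhibitor gene CDKN1A at 5.59 ± 0.292 and 4.45 ± 0.635 TPM (camera adjusted p = 0.829). Among 18 p53 targets PLK3 was at an unadjusted p below 0.05, with 10.4 ± 0.141 and 8.41 ± 0.131 TPM (camera adjusted p = 0.818). Homologous recombination genes had 0 of 17, with FANCD2 at 3.08 ± 1.26 and 2 ± 0.415 TPM (camera adjusted p = 0.970), and apoptosis genes 1 of 25, BIK at 22.9 ± 1.30 and 26.7 ± 1.62 TPM (camera adjusted p = 0.829).

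Signalling and metabolic lists of MHCC-97H were similar. The interferon list had 1 of 14 at an unadjusted p below 0.05, OAS3 at 7.81 ± 0.254 and 6.11 ± 0.4997 TPM (camera adjusted p = 0.829), and the NF-kB list 0 of 15, with NFKBIA at 13.5 ± 2.12 and 10.7 ± 1.36 TPM (camera adjusted p = 0.970). Notch and Hedgehog genes had 1 of 7, the ligand gene JAG2 at 8.71 ± 0.854 and 11.2 ± 1.63 TPM (camera adjusted p = 0.818), and Wnt targets 0 of 8, with CCND1 at 29.1 ± 2.74 and 24.6 ± 2.63 TPM (camera adjusted p = 0.843). Cholesterol genes had 1 of 24, TM7SF2 at 1.35 ± 0.735 and 2.18 ± 0.410 TPM (camera adjusted p = 0.970), and fatty acid genes 0 of 15, with SCD at 26.2 ± 5.23 and 22.5 ± 4.68 TPM (camera adjusted p = 0.829). Glycolysis and hypoxia genes had 0 of 26, with HK1 at 19.9 ± 3.50 and 16.9 ± 3.10 TPM (camera adjusted p = 0.829). Mesenchymal genes had 0 of 21, with COL5A1 at 19.03 ± 3.34 and 22.2 ± 3.31 TPM (camera adjusted p = 0.970), and epithelial junction genes 1 of 14, CRB3 at 15.6 ± 1.82 and 18.5 ± 1.77 TPM (camera adjusted p = 0.829). Ribosomal protein genes had 0 of 51, with RPS28 at 1533 ± 65.5 and 1627 ± 41.3 TPM (camera adjusted p = 0.628). Nuclear respiratory chain genes had 0 of 35, with SDHA at 66.8 ± 9.73 and 57.4 ± 9.49 TPM (camera adjusted p = 0.970), and mitochondrially encoded genes 0 of 13, with MT-CO2 at 8683 ± 1593 and 8449 ± 765 TPM (camera adjusted p = 0.940). The median, the mean and the test direction differed in sign for 11 lists in MHCC-97H: outer kinetochore, G1/S, cholesterol, fetal liver, mesenchymal, epithelial junction, Notch and Hedgehog, apoptosis, homologous recombination, ribosomal protein and mitochondrially encoded genes.

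**Figure D3:**
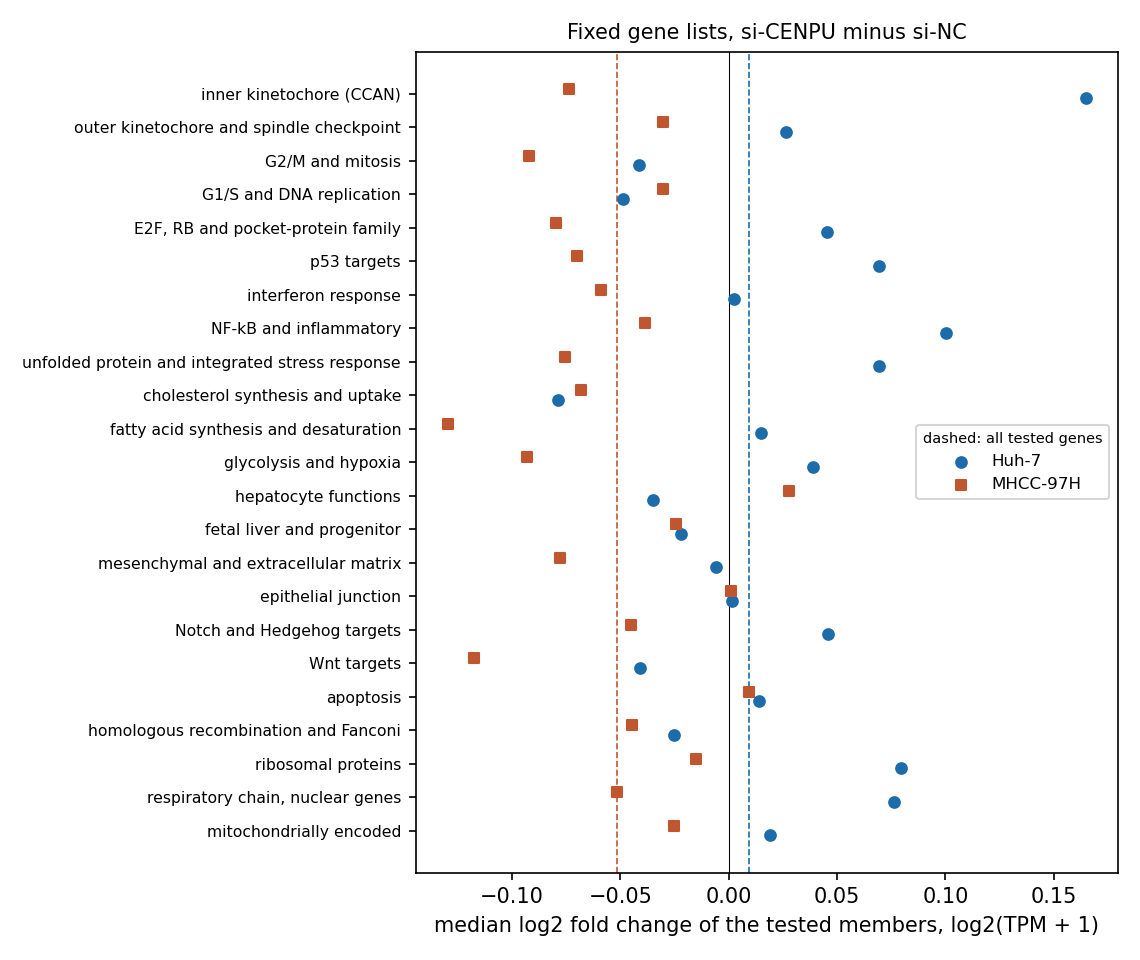
Median log2 fold change, si-CENPU minus si-NC on the log2(TPM + 1) scale, of the tested members of each of 23 fixed gene lists in Huh-7 (circles) and MHCC-97H (squares); dashed lines mark the median of all tested genes (0.01 and -0.05). The inner kinetochore list has the highest median in Huh-7 (0.16), and 20 of the 23 medians in MHCC-97H lie below 0.

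The responses of the lines were compared by the interaction contrast, MHCC-97H minus Huh-7, and 1 gene passed. MAP2K4, which rose in Huh-7, stood at 1.02 ± 0.272 and 0.620 ± 0.121 TPM in MHCC-97H (SD, n = 3; log2 -0.31, limma adjusted p = 1). The difference of log2 changes was -2.10 (SE 0.237, limma adjusted p = 0.0281). With 1 library left out, this call held in 5 of 12 fits (adjusted p from 0.0117 to 0.165). It was lost without any 1 of the 3 Huh-7 si-CENPU libraries, without MHCC-97H si-NC replicate 1 or 2, and without MHCC-97H si-CENPU replicate 2 or 3. It was also lost with a pseudocount of 0.1 (adjusted p = 0.151) or 0.5 (0.0541), and it held in 13 of the 23 alternative fits that tested it, over which its adjusted p ran from 0.00447 to 0.165. At an unadjusted p below 0.05 the interaction held 383 genes, 154 positive and 229 negative, against 554.4 by chance. Without MHCC-97H si-NC replicate 3 it held 674 and without Huh-7 si-CENPU replicate 1 it held 601, both above 554.4, a count whose spread under chance was not computed. The response of ADAM15 was not shown to differ between lines. Huh-7 stood at 18.5 ± 1.59 and 19.9 ± 1.58 TPM, and the interaction was 0.67 (limma adjusted p = 0.873). NR1H3 stood at 12.3 ± 1.67 and 13.8 ± 1.75 TPM in MHCC-97H (interaction 1.65, adjusted p = 0.873). FAM174B was at 1.84 ± 0.598 and 1.03 ± 0.162 TPM in Huh-7 and at 0.3 ± 0.246 and 1.39 ± 0.102 TPM in MHCC-97H (interaction 1.37, adjusted p = 0.873). The ciliary rootlet gene CROCC (interaction 0.93) and ZFYVE9, which encodes the SMAD anchor SARA (interaction -0.86), had an adjusted p of 0.999 each.

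Across the 11088 tested genes, log2 changes in the lines were not correlated (Pearson r = -0.01, Spearman rho = 0.02), and 47.9% of genes had the same sign. These values are across genes, which are not independent replicates. No gene was called by limma in both lines in either direction. At an unadjusted p below 0.01, which was chosen after the values were seen, 117 genes in Huh-7 and 104 in MHCC-97H remained, of which 14 were higher in both lines, 2 lower in both and 1 opposite. Independent lists give 0.427 higher and 0.155 lower.

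**Figure D4:**
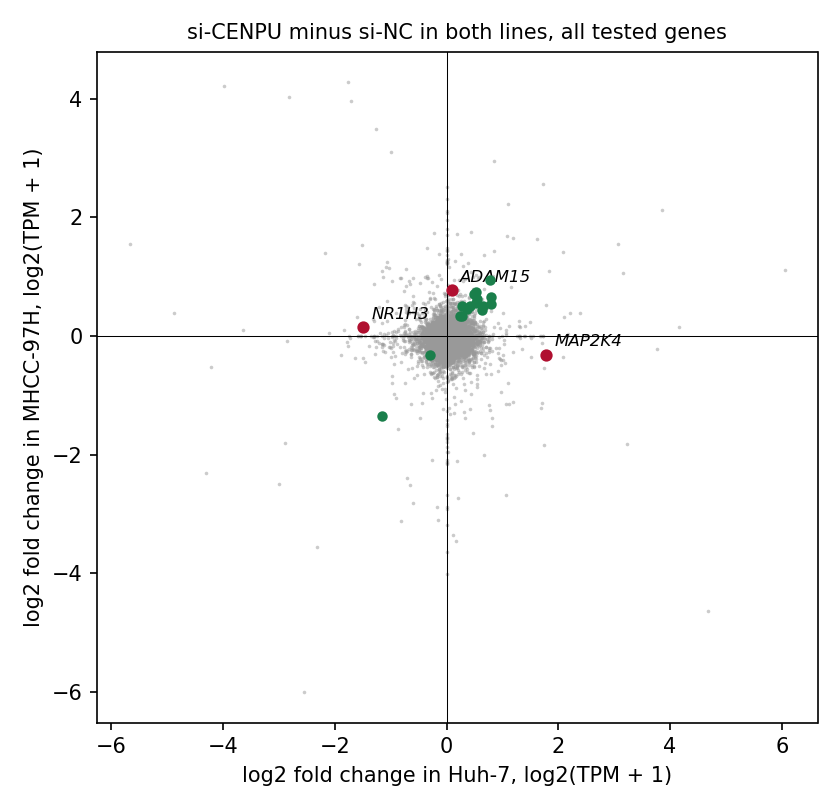
Log2 fold change (si-CENPU minus si-NC, log2(TPM + 1)) in Huh-7 on the x axis against MHCC-97H on the y axis for 11088 tested genes, 1 grey dot each; green dots are the 16 genes with an unadjusted p below 0.01 in both lines and the same direction, and red dots are MAP2K4, ADAM15 and NR1H3. The cloud has no slope (Pearson r = -0.01), and 14 of the green dots lie in the quadrant that is positive in both lines.

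Markers of other cell types were low or gave no call. Leukocyte markers included CD68 at 38.1 ± 2.16 and 40.7 ± 5.21 TPM and LYZ at 18.7 ± 6.54 and 20.9 ± 5.08 TPM in Huh-7. In MHCC-97H, CD68 stood at 17.9 ± 1.002 and 16.8 ± 1.10 TPM. The fibroblast marker MFAP5 stood at 4.88 ± 1.46 and 5.07 ± 0.900 TPM in MHCC-97H and was listed at 0 in all 6 Huh-7 libraries. COL3A1 stood at 5.70 ± 0.620 and 4.98 ± 0.571 TPM in Huh-7. The endothelial marker ESAM stood at 45.7 ± 1.96 and 45.4 ± 3.97 TPM in MHCC-97H, where the other endothelial markers averaged under 0.5 TPM. No erythroid marker reached the expression limit, the highest being HBA2 at a mean of 0.745 TPM in MHCC-97H. Of the cervical and kidney line markers, SIX2 stood at 33.0 ± 1.24 and 36.7 ± 1.16 TPM in MHCC-97H, and the highest in Huh-7 was EYA1 at a mean of 0.898 TPM. Among the 9 tested genes of these 5 lists limma called 0 in either line, and 0 reached an unadjusted p below 0.05.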

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

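The 3 tests of MAP2K4 against reads of a neighbouring gene, GC content and a single library were chosen only after the result was seen. The test over other splits of the samples was fixed beforehand. No formal test of whether single libraries were outliers was run, since groups of 3 samples are small. Each library was left out in turn instead.

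The response of MAP2K4 to si-CENPU differed between the lines by the interaction test, by -2.10 on the log2 scale (MHCC-97H minus Huh-7). After removal of each library's GC trend the difference was -1.96 (SE 0.194, adjusted p = 0.00941), and with 1 library left out its smallest size was -1.98, without Huh-7 si-NC replicate 1, although the call was lost in 7 of the 12 fits. Reads of a neighbour cannot be told apart from those of MAP2K4, since the 4 annotated genes within 20 kb were listed at 0 TPM in Huh-7 si-CENPU, which can be a failed estimate. Chance was not excluded: 58 of 100 drawn splits within both lines gave at least the 1 call of the real labels, and the highest other split gave 4. A response of Huh-7 that MHCC-97H lacks, or an effect of the duplex on a gene other than its target, may be the source, and neither was tested.

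For the calls within a line the 10 splits of 6 samples are too few for a share under 0.05. The real split gave 1 call in each line, and the highest other split gave 2 in each. Counting the real split, 6 of the 10 splits in Huh-7 and 7 of the 10 in MHCC-97H gave at least as many calls. Chance was therefore not excluded for either call.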

How the results depend on the processing

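No called result changed direction under the alternatives run. The GC correction, the filter within each line, the test of protein-coding genes and the list tests that joined an estimated correlation to another alternative were chosen only after the results were seen. Causes were not tested unless named. Depth is unknown, so its limit on these values cannot be given. The main counts were 1 higher and 0 lower in each line, 1 for the difference between lines and 0 lists, with CENPU at -0.41 in Huh-7 and -0.59 in MHCC-97H. A pseudocount of 0.1 gave 5 higher and 6 lower in Huh-7, 0 higher in MHCC-97H, 0 for the difference and 1 list, with CENPU at -1.22 and -1.43. A pseudocount of 0.5 gave 0 for the difference and 1 list, with CENPU at -0.64 and -0.87, since a smaller pseudocount stretches low values. With no filter on low values there were 3 higher and 1 lower in Huh-7, 3 higher and 4 lower in MHCC-97H, and 6 for the difference. A mean TPM of at least 5 left 0 higher in Huh-7 and 0 for the difference, since MAP2K4 was then not tested. TMM-type scaling gave 1 lower in Huh-7, 6 higher and 1 lower in MHCC-97H, and 2 for the difference. Quantile normalization gave 2 higher and 1 lower in Huh-7 and 6 higher and 1 lower in MHCC-97H, with CENPU at -0.59 and -0.45. Rescaling without mitochondrial and the 100 most abundant genes gave 1 list, with CENPU at -0.73 and -0.92. Moderation without a trend gave 0 higher in MHCC-97H, and so did an added limit of 2-fold. With each line fitted alone there were 0 higher in Huh-7, 0 higher in MHCC-97H and 1 list. The filter within each line, fitted alone, gave 0 higher in both lines. The GC correction gave 2 higher and 1 lower in Huh-7, 7 higher and 2 lower in MHCC-97H, and 1 list, and protein-coding genes alone gave 1 list.

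The replicate number did not pair the samples: deviations of same-numbered si-NC and si-CENPU libraries correlated between -0.09 and 0.03 in Huh-7 and between -0.09 and 0.13 in MHCC-97H, and not every library correlated best with its own number. As a block it gave 0 higher in Huh-7, 0 higher in MHCC-97H, 0 for the difference and 2 lists. The adjusted p under the block was 0.0628 for MAP2K4 in Huh-7, 0.105 for its difference between lines and 0.467 for ADAM15 in MHCC-97H.

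The list past the threshold was hepatocyte functions in MHCC-97H with both pseudocounts, each line alone, the GC correction and protein-coding genes, and ribosomal proteins in Huh-7 with the rescaling (adjusted p = 0.0222). The block gave both. With an estimated correlation under these settings none passed: the adjusted p of hepatocyte functions was 0.295 with each line alone, and the others were between 0.961 and 0.997.

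With each library left out in turn, Huh-7 had 0 to 3 genes higher and 0 to 2 lower, MHCC-97H 0 to 2 higher and 0 to 2 lower, and the difference 0 to 4. Calls in both lines stayed at 0 in the same and in opposite directions. CENPU ran from -0.52 to -0.32 in Huh-7 and from -0.67 to -0.52 in MHCC-97H, the correlation between lines from -0.05 to 0.03, and lists from 0 to 2. In Huh-7, limma called 3 genes without si-NC replicate 1, 2 without si-NC replicate 2, 4 without si-NC replicate 3 or without si-CENPU replicate 3, and 0 without si-CENPU replicate 2. In MHCC-97H it called 4 without MHCC-97H si-NC replicate 2, and ADAM15 alone without Huh-7 si-NC replicate 1. Without MHCC-97H si-NC replicate 1, si-CENPU replicate 1 or si-CENPU replicate 3 it called 1 gene that was not ADAM15, and without any of the other libraries 0. For the difference between lines it called 3 genes without Huh-7 si-NC replicate 1, 4 without Huh-7 si-NC replicate 3, 2 without MHCC-97H si-NC replicate 2 or si-CENPU replicate 1, and 0 without Huh-7 si-CENPU replicate 1 or 2 or MHCC-97H si-CENPU replicate 2. Ribosomal proteins in Huh-7 passed without Huh-7 si-NC replicate 1 (adjusted p = 0.0437) and without si-CENPU replicate 1 (0.00798). Hepatocyte functions in MHCC-97H passed without Huh-7 si-NC replicate 1, MHCC-97H si-NC replicate 3 (0.0436) and MHCC-97H si-CENPU replicate 2 (0.0189), and so did ribosomal proteins in MHCC-97H without the last. With an estimated correlation and the same library left out, none of these list tests passed (adjusted p from 0.982 to 0.999).

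Of the values of single named genes, 3348 were unchanged under other settings: the call was kept, or an uncalled value moved by under 1 SE of the main fit. Another 126 stayed uncalled but moved by at least 1 SE, 25 newly passed and 11 no longer passed. With a library left out the numbers were 3043, 65, 4 and 18. Many of the unchanged values could not move. The log2 change within a line stays the same under another filter or moderation, and when a library of the other line is left out. The counts of unchanged values are therefore no measure of robustness.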

Other observations

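All tests below on genes shared by the lines and on genes near 0 in Huh-7, and the fit of the average of both lines, were chosen only after the result was seen.

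The 14 genes higher in both lines at an unadjusted p below 0.01 included EMC6 and the receptor gene OGFR, described above, with OGFR at 28.2 ± 3.28 and 40.3 ± 2.23 TPM in MHCC-97H, and PCNX3 at 12.4 ± 1.47 and 17.9 ± 1.69 TPM in Huh-7 (SD, n = 3). RGS19, a regulator of G protein signalling, stood at 7.62 ± 0.331 and 11.5 ± 0.645 TPM in Huh-7 and at 10.4 ± 2.15 and 17.9 ± 0.811 TPM in MHCC-97H. The Mediator subunit MED11 stood at 7.68 ± 0.385 and 14.1 ± 0.723 TPM in Huh-7 and at 6.07 ± 1.49 and 9.22 ± 1.17 TPM in MHCC-97H. Tropomyosin 4 (TPM4) stood at 17.1 ± 4.85 and 29.6 ± 6.396 TPM in Huh-7 and at 24.2 ± 5.92 and 46.7 ± 6.05 TPM in MHCC-97H. Others were FMC1, SPINDOC, TLE5, MTSS2, CCDC107, SERF1B and THAP7-AS1. COMMD5, lower in both, stood at 39.0 ± 1.41 and 31.4 ± 0.776 TPM in Huh-7 and at 57.4 ± 4.21 and 45.9 ± 2.69 TPM in MHCC-97H. In a fit of the average of both lines EMC6 was the 1 gene called (log2 0.55, SE 0.0624, limma adjusted p = 0.0310), with PCNX3 and OGFR at 0.0516 and RGS19 at 0.0521, and 450 genes were at an unadjusted p below 0.05.

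This excess of genes higher in both lines was weighed against 3 technical or chance explanations. Of 100 splits drawn within both lines, 1, the real one, gave as many genes in the same direction, 16. The highest other gave 12, and the median of the others was 1. The limit of 0.01 was chosen after the values were seen, so this share does not exclude chance. GC content as the whole source was argued against, since after its removal 11 of the 14 were still higher in both lines at this limit and 14 were positive in both. In all, 21 genes were then higher in both and 5 opposite, against 14 and 1 before. The correction also raised the genes at an unadjusted p below 0.05, to 807 in Huh-7 and 548 in MHCC-97H. The rise to 21 therefore says nothing about the source. With any 1 library left out, 7 to 10 genes, 6 to 10 of the 14 among them, were higher in both and 0 to 3 opposite. There were 10 higher without Huh-7 si-CENPU replicate 2, MHCC-97H si-NC replicate 2 or MHCC-97H si-CENPU replicate 3, and 7 to 9 without any of the others. The excess therefore did not need any single library. These fits show no more than that, since 1 library enters the contrast of 1 line only. The 14 were also picked with all libraries present. A response to loss of CENPU in both lines, or to the si-CENPU duplex itself, may be the source, and these remain as hypotheses because a single duplex name was given for both lines.

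Levels listed for marker genes differed between the lines whatever the treatment. Genes of plasma proteins were abundant in Huh-7 and near 0 in MHCC-97H: APOA1 averaged 4354 TPM over 6 Huh-7 libraries and 0.388 TPM in MHCC-97H, TTR 2030 and 0.208 TPM, APOC3 651 and 0.105 TPM. The fetal liver protein gene AFP averaged 292 and 0.0533 TPM. MHCC-97H had higher VIM, at 188 ± 35.1 against 61.3 ± 12.7 TPM (SD, n = 6). KRT7 averaged 566 TPM in MHCC-97H and 0.172 TPM in Huh-7. A level near 0 in either line can be a failed estimate, KRT7 in Huh-7 included. These are differences of line and were not tested against treatment.

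Some genes that dividing or respiring cells use were listed near 0 in Huh-7 and were abundant in MHCC-97H. CDK4 read 0 to 0.32 TPM in the Huh-7 libraries and averaged 498 TPM in MHCC-97H, PCNA read 0.01 to 0.23 TPM against 37.6 TPM, and MT-CO2 read 0 to 0.04 TPM against 8566 TPM. In all, 121 protein-coding genes averaged under 0.5 TPM in Huh-7 and at least 20 TPM in MHCC-97H, and 118 the reverse. Reads counted for an overlapping gene could explain 3 of the 121, and 15 had a copy elsewhere in GENCODE 29, a pseudogene or related gene that shared at least 10% of their 31-base words, of which 1 had a copy at 1 TPM or more in Huh-7, which argues against either as the source for most. For MT-CO1, outside the 121 at 0 to 10.95 TPM in the Huh-7 libraries and a mean of 4678 TPM in MHCC-97H, reads counted for its pseudogene copy MTCO1P12, which averaged 1889.6 and 1221 TPM, remain open. For most of the 121, failed estimates in Huh-7 cannot be told apart from absent transcripts without reads. For 2 of the 13 mitochondrially encoded genes, MT-CO2 and MT-CO3, which were among the 121, other values argue against absence. In Huh-7, 10 of the 13 averaged over 500 TPM, with MT-ATP6 at 2103 ± 578 and MT-ND4 at 1935 ± 484 TPM (SD, n = 6). No biological explanation was tested, and the values of the 121 genes in Huh-7 say little about a response.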
